A study of Drosophila melanogaster with 4 samples.

How the data were processed

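H3 ChIP-seq clusters of wild-type Oregon-R embryos at 14 to 16 h were analysed from 3 lists, 1 per ChIP replicate and 1 for the whole series. Per the labels' protocols, embryos no older than 16 h were fixed with 1.8% formaldehyde and the chromatin was incubated with antibody for 15 h. Per the labels, each of the 2 input libraries served the cluster list of the ChIP replicate with its number. Bowtie 0.12.7 is named in the submitters' processing notes. Per the file headers, positions are on FlyBase release 5. The cluster caller, its threshold and the way in which the replicates were combined into the series-wide list are not given in the sources used here.

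Each cluster was deposited with a start, an end and 1 score, which is the authors' own value and was used to describe, rank and filter clusters and to relate overlapping clusters. The deposited score is on a log2 scale. This was taken from the values, since the files do not state it: in base 2, 99.7% of series-wide scores, 99.1% in replicate 1 and 100% in replicate 2 differed from the most frequent score of their list by the logarithm of a ratio of whole numbers (denominator up to 1000, relative tolerance 1e-10), against 2.05% or fewer in base e or 10. That the score compares ChIP with input is not stated in the files. Read depth is unknown, so no interval for reads could be given, and the number of clusters per list sets the precision. Binomial intervals cover counting error only. Start and end were both even in 100% of series-wide clusters and in 25.6% and 26.9% of clusters of the replicates. This processing step differed between the lists, and its origin is not given in the sources used here.

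Overlap was at least 1 bp unless stated. Overlap was tested with 1000 circular shifts of one list within each chromosome, one-sided for an excess. Medians were compared with 100000 permutations of cluster labels, two-sided. Correlations are Spearman's rho and Pearson's r with 100000 permutations, two-sided, for pairs of a replicate 1 cluster with the replicate 2 cluster of largest overlap. Shares of clusters per sequence group were compared with shares of length by exact two-sided binomial tests with Clopper-Pearson intervals at 95%. Benjamini-Hochberg adjustment was made over sequence groups and lists, over the lists and measures of the comparison of shared with unshared clusters, and over those of the comparison of X with the autosome arms. The threshold was 0.05. Uextra was left out of the lengths, a choice made after the data were examined. Bootstrap intervals used 10000 draws. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

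The shift test was tested on simulated data for the comparison of replicate 1 with replicate 2, with lists of 3717 and 2198 clusters in 100 simulations. Without shared clusters 5.0% had p under 0.05, and with 200 planted shared clusters 100% did, with 172 ± 13.2 recovered as excess overlap (SD). Simulated clusters were placed uniformly along each chromosome. The rate for lists that share dense and sparse regions, as the real ones do, was therefore not tested. The median test called 5.25% and the rank correlation 4.25% of 400 simulations without an effect.

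Named clusters were chosen before the data were examined: the 10 highest-scored and the 10 longest series-wide clusters that overlap both replicates, and the 5 longest of each replicate that overlap none of the other. Alternatives set at that time were the upper 50% of each list by score, neighbours within 1000 bp merged, only the 6 arms 2L, 2R, 3L, 3R, 4 and X, stricter overlap rules, lists of equal size, covered bases in place of clusters, removal of clusters under 200 bp, and each replicate alone. No cluster proved to be under 200 bp, so that removal could change nothing. Local shifts, the differences in length and score that shifted lists give, a minimum length, the treatment of Uextra and correlations by chromosome were added after the data were examined.

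Comparisons of clusters with gene features, with gene lists (Hox genes, Polycomb-regulated genes, ribosomal protein genes and others) and with base composition and repeats were planned but not run. They need the annotation or the sequence of release 5, which was not used here, and the gene names at hand belong to release 6.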

Results

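Histone H3, a core protein of the nucleosome, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in wild-type Oregon-R embryos of *Drosophila melanogaster* collected at 14 to 16 h of development. The series comprised 4 libraries, namely 2 ChIP replicates made with 1 anti-H3 antibody and 2 input replicates of chromatin DNA without immunoprecipitation. Each input served its own ChIP replicate, so the inputs enter only through the enriched regions called in that replicate. The values available were 3 lists of enriched regions (clusters), 1 for each ChIP replicate and 1 for the whole series, with a position and the authors' log2 score for each cluster. Read numbers per library were unknown. The labels do not say that the replicates came from separate embryo collections, so their spread may be technical. Clusters within a list are not independent replicates, and each p-value below describes the lists and not a population of embryos. All positions are on FlyBase release 5, and no annotation of that release was used here, so clusters are named by chromosome and position.

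Clusters of H3 enrichment covered a larger part of the chromosome arms in the series-wide list than in either replicate. The series-wide list held 18424 clusters over 30.4 Mb, replicate 1 held 3717 over 6.06 Mb, and replicate 2 held 2198 over 3.48 Mb, on all sequences. The clusters on 2L, 2R, 3L, 3R, 4 and X covered 24.5%, 4.93% and 2.82% of the 120.4 Mb of these arms, in the same order. The replicate mean was 2957.5 ± 1074 clusters (SD, n = 2), and the series-wide list was 6.23 times as long. Median cluster length was 1452 bp in the series-wide list, 1520 bp in replicate 1 and 1487 bp in replicate 2. The shortest cluster was 1001 bp in the series-wide list and 1301 bp in both replicates. The median of the authors' score was 0.42, 0.55 and 0.69 in the series-wide list, replicate 1 and replicate 2, on a log2 scale.

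In the full lists clusters were most frequent on 2R and 3R, and they were rare on chromosome 4, in the placed heterochromatin sequences and in the unplaced sequence U. The number of clusters relative to that given by sequence length was 1.26 on 2R and 1.29 on 3R in the series-wide list, and 1.41 ± 0.0045 and 1.33 ± 0.029 as the mean of the replicates (SD, n = 2). Chromosome 4, a small chromosome rich in heterochromatin, carried 17 clusters in the series-wide list against 178.3 given by its length, a ratio of 0.0954. It carried 3 clusters in replicate 1 and 0 in replicate 2. The ratio was 0.253 in the placed heterochromatin and 0.220 on U in the series-wide list, with replicate means of 0.167 ± 0.0040 and 0.142 ± 0.041 (SD, n = 2). Uextra, a further collection of unplaced sequence, carried 0 clusters in all 3 lists and was left out of the lengths. Lengths are those of whole sequences, and the part on which reads could be placed was not measured. Few clusters for a given length thus need not mean little H3.

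For these 5 sequence groups the departure from length passed the exact two-sided binomial test in every list. In the series-wide list the Benjamini-Hochberg adjusted p over all sequence groups and lists was 3.4e-47 for 2R, 1.2e-80 for 3R and 9.6e-54 for chromosome 4. In replicate 2, whose list was the shortest, it was 3e-14, 7.3e-15 and 1.8e-09. Arms 2L and 3L lay near 1, at 1.07 and 1.09 in the series-wide list, though both passed there (exact binomial test, adjusted p = 1.8e-05 and 1.1e-08). Neither kept its direction when only the 6 arms entered the lengths (0.956 and 0.974) or when only the upper 50% of clusters by score was counted (0.870 and 0.947). Replicate 1 gave 1.06 for 2L and 1.12 for 3L, and only 3L passed (exact binomial test, adjusted p = 0.13 and 0.0011). Replicate 2 gave 0.975 for 2L and 1.05 for 3L, with adjusted p of 0.62 and 0.27. The X chromosome stood at 0.927, 0.833 and 0.930 in the series-wide list, replicate 1 and replicate 2, and the departure missed the threshold in replicate 2 (exact binomial test, adjusted p = 0.17). With neighbours within 1000 bp merged, the series-wide ratio of X was 0.988 and missed the threshold as well (exact binomial test, adjusted p = 0.55). With Uextra in the lengths it was 1.12. With only the 6 arms in the lengths, X stood at 0.826, 0.732 and 0.820 in the series-wide list, replicate 1 and replicate 2. It then passed in every list (exact binomial test, adjusted p = 4.2e-29, 4.9e-15 and 7.7e-05). Among the upper 50% of clusters by score X had the highest ratio in every list (1.52, 1.33 and 1.59), above 2R (1.15, 1.29 and 1.27) and 3R (1.09, 1.19 and 1.11), and 3R in replicate 2 missed the threshold (exact binomial test, adjusted p = 0.094). Scores were higher on X in every list, as given below, so such a cut keeps a larger share of X clusters.

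**Figure D1:**
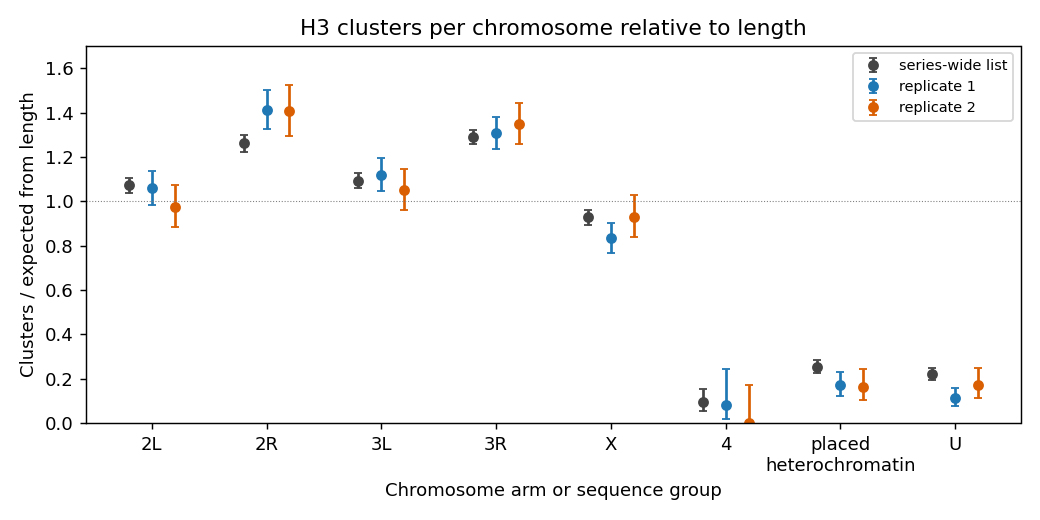
Number of H3 clusters divided by the number given by sequence length (vertical axis, no unit) for each chromosome arm, the placed heterochromatin and U, in the series-wide list and both replicates. Bars are exact 95% binomial intervals; 2R and 3R lie above 1 and chromosome 4, heterochromatin and U lie below 0.3 in every list.

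The X chromosome had fewer clusters per Mb than the autosome arms 2L, 2R, 3L and 3R, and its clusters had higher scores. Cluster density on X was 0.784 times that of the autosome arms in the series-wide list (exact 95% interval 0.752 to 0.817). The replicates gave 0.681 and 0.777, a mean of 0.729 ± 0.068 (SD, n = 2). The median score on X exceeded that of the autosome arms by 0.067 in the series-wide list, 0.079 in replicate 1 and 0.12 in replicate 2 on the log2 scale. Each of these differences had an adjusted p of 2e-05 in a two-sided permutation test of medians, from the smallest p that 100000 permutations can give. Median length on X differed from that of the autosome arms by -32, -16 and -8 bp, and none passed the threshold in the same permutation test (adjusted p = 0.052, 0.36 and 0.67). The direction of the density difference turned with a cut by score. Among the upper 50% of series-wide clusters by score, X held 1.50 times as many clusters per Mb as the autosome arms. That cut kept 2246 of 2741 clusters on X and 6468 of 15064 on the autosome arms. Since scores on X were higher, this turn restates the score difference and is no separate result on density. The comparisons of X with the autosome arms were chosen after the data were examined.

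**Figure D2:**
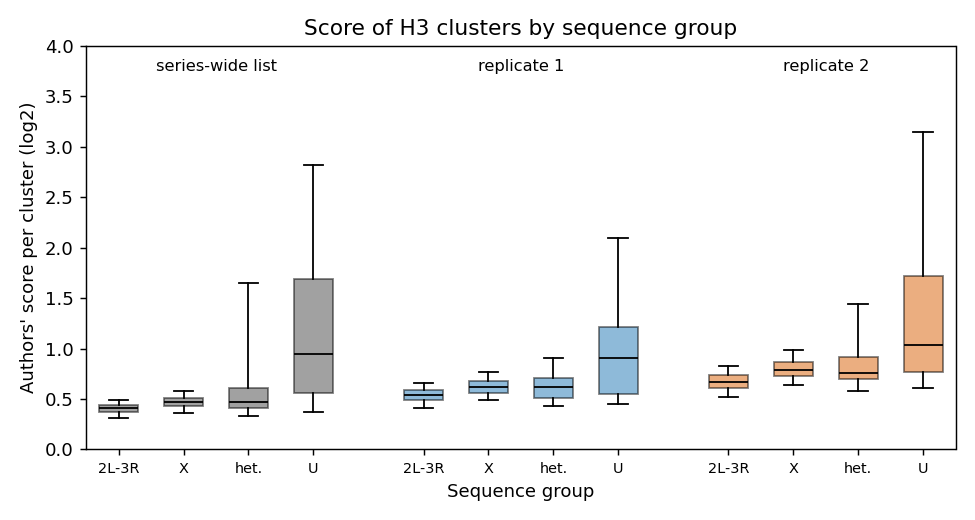
Authors' log2 score per cluster (vertical axis) on the autosome arms (2L-3R), X, the placed heterochromatin (het.) and U, for each list; boxes span the quartiles with the median as a line, and whiskers run from the 5th to the 95th percentile. In every list the X box sits above that of the autosome arms, and U has the highest median.

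Along the arms, the replicates placed their clusters in the same broad regions. Over the 117 complete 1-Mb windows of 2L, 2R, 3L, 3R and X, the number of clusters in replicate 1 followed that in replicate 2 with Spearman's rho = 0.813 and Pearson's r = 0.815 (permutation p = 1e-05 for both, the smallest possible; windows are not independent replicates). The rank correlation was 0.780 over the autosome windows and 0.671 over the 22 windows of X. The series-wide list had a median of 155 clusters per window. The densest window, 3R 25000001-26000000, held 231, with 59 in replicate 1 and 31 in replicate 2. The sparsest, 3L 23000001-24000000, held 35, with 4 and 1 in the replicates.

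The ends of the arms next to the centromeres were poor in clusters. In the 2 Mb next to the centromere of 2L, 2R, 3L, 3R and X, the series-wide list had 737 clusters, 0.495 times the number after random circular shifts of the arms. The replicates gave 0.403 and 0.497, a mean of 0.45 ± 0.066 (SD, n = 2). The p was 0.001 in each list, the smallest that 1000 shifts can give in this one-sided permutation test. Relative to the rest of the same arm, mean density over the replicates was 0.166 ± 0.022 for 2L, 0.276 ± 0.058 for 2R, 0.399 ± 0.047 for 3L, 0.528 ± 0.141 for X and 0.759 ± 0.078 for 3R (SD, n = 2). In the series-wide list 2L, 2R and 3L lay close together, at 0.333, 0.344 and 0.358, with 0.575 for X and 0.750 for 3R. The windows and the centromere ends were also chosen after the data were examined. How much of these ends reads could be placed on was likewise not measured.

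**Figure D3:**
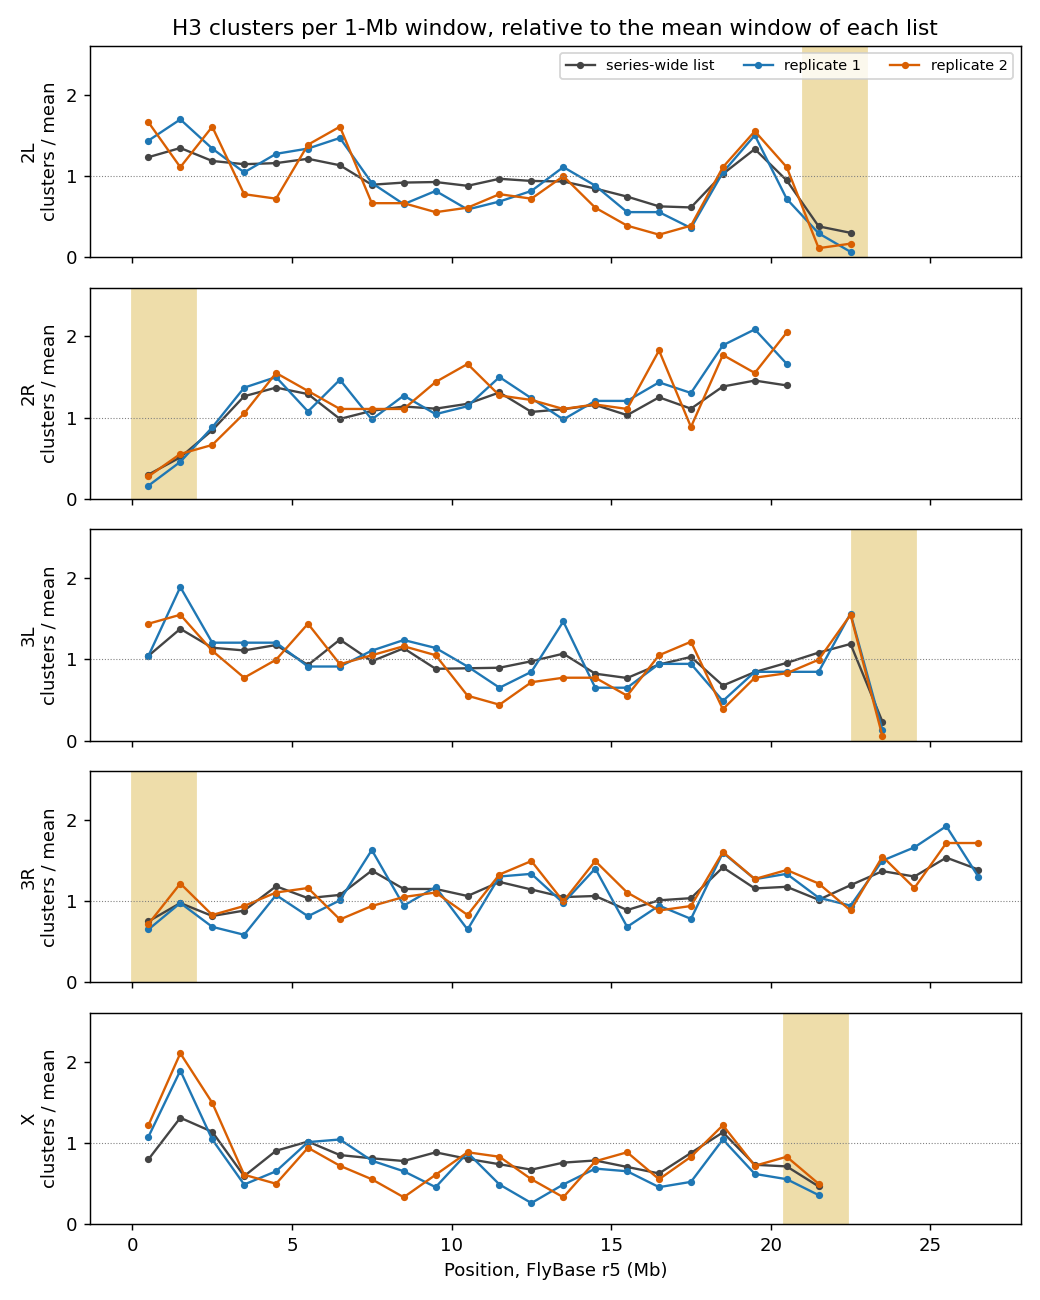
Clusters per 1-Mb window relative to the mean window of the same list (vertical axis, no unit) along 2L, 2R, 3L, 3R and X (horizontal axis, position in Mb, FlyBase release 5), with the 2 Mb next to each centromere shaded. The 3 lists rise and fall together, and the shaded windows of 2L and 2R lie below 1 in all 3.

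Whether single clusters repeated between the replicates was asked by overlap of at least 1 bp. Most did not, although overlap was more frequent than for shifted positions. Of the 3717 clusters of replicate 1, 514 overlapped a cluster of replicate 2 (13.8%, exact 95% interval 12.7 to 15.0), against 5.76% after shifts within chromosomes, a ratio of 2.40. Of the 2198 clusters of replicate 2, 511 overlapped replicate 1 (23.2%, interval 21.5 to 25.1, against 9.69%). In this one-sided permutation test both had p = 0.001, the smallest that 1000 shifts can give. When shifts were kept to 20 to 100 kb, so that regional density was retained, the ratios were 2.00 and 2.01.

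Clusters found in both replicates were longer in the median than those found in 1 replicate, a difference that shifted positions also gave in part. In replicate 1 the medians were 1609.5 and 1512 bp, a difference of 97.5 bp, and in replicate 2 they were 1545 and 1474 bp, a difference of 71.0 bp (adjusted p = 2e-05 for both, two-sided permutation test of medians). That test takes no account of the chance overlap of longer clusters. After shifts within chromosomes the differences averaged 30.0 bp (central 95% -20.5 to 93.5) and 19.7 bp (-18 to 60.0), and against these the adjusted permutation p was 0.051 in replicate 1 and 0.028 in replicate 2. Against local shifts it was 0.051 in both, past the threshold in neither. The median score of shared clusters was higher by 0.019 in replicate 1 (adjusted permutation p = 0.00011, 0.024 against shifts and 0.051 against local shifts). In replicate 2 the score difference was 0.0019 and missed the threshold (adjusted permutation p = 0.83), and it turned to -0.0036 when overlap had to reach 50% of both clusters. Over the 514 overlapping clusters of replicate 1, the scores of the replicates were related with rho = 0.409 and r = 0.482 (permutation p = 1e-05 for both; across clusters). The rank correlation was 0.319 for the 438 pairs on 2L, 2R, 3L and 3R (permutation p = 1e-05) and 0.223 for the 67 pairs on X, where it missed the threshold (p = 0.069) while r = 0.265 passed it (p = 0.029).

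The series-wide list took in nearly all clusters of both replicates and many regions listed in neither. It overlapped 98.2% of replicate 1 clusters (44.3% after shifts) and 95.9% of replicate 2 clusters (43.7% after shifts), each with a permutation p of 0.001. Of its own clusters, 19.6% overlapped replicate 1 and 11.5% overlapped replicate 2, against 9.73% and 5.70% after shifts. By its name the series-wide list is a set of the same replicates. An excess over shifted positions was therefore built in, and these tests give no independent support. Counted once each, 560 series-wide clusters (3.04%) overlapped both replicates, 3056 only replicate 1, 1555 only replicate 2, and 13253 (71.9%, exact 95% interval 71.3 to 72.6) neither. Their median lengths were 2721, 1889, 1825 and 1299 bp. Ordered by length, the share that overlapped a replicate ran from 4.07% in the shortest 1843 clusters to 69.0% in the longest 1843. Ordered by score in 10 classes of equal size, it ran from 23.5% in the lowest class to 34.1% in the next to highest and 29.6% in the highest. The share that overlapped both replicates rose with score from 0.760% in the lowest class to 8.57% in the highest, and with length from 0% to 17.9%. Longer clusters also overlap more often by chance. The replicates held no cluster under 1301 bp, whereas the series-wide list started at 1001 bp. Low shares among its shortest clusters may therefore in part be built in by the different minimum lengths. Of the clusters found in replicate 1 alone, 3136 of 3203 (97.9%) lay in the series-wide list, and of those found in replicate 2 alone, 1596 of 1687 (94.6%).

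**Figure D4:**
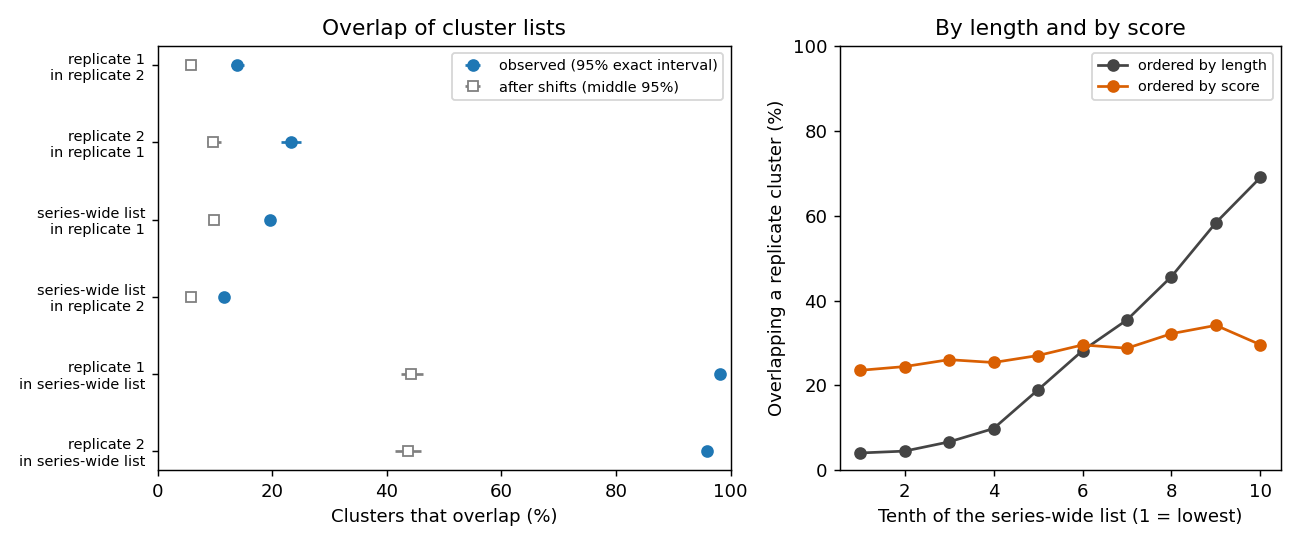
Left, share of clusters (horizontal axis, percent) of one list that overlapped another by at least 1 bp, with exact 95% intervals, beside the mean and central 95% of 1000 shifted lists. Right, share of series-wide clusters that overlapped a replicate (vertical axis, percent) in 10 classes of equal size by length or score (horizontal axis, 1 lowest); the share rises from 4.07% to 69.0% with length and stays between 23.5% and 34.1% with score. The replicates hold no cluster under 1301 bp, which may lower the share in the shortest classes.

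Single regions are given by the rule set before the data were examined. Of the 10 series-wide clusters with the highest score that overlapped both replicates, 6 lay on X, 2 on U and 2 on 3L. The highest was U 1041494-1043696, with a series-wide score of 0.84 and scores of 0.84 and 0.96 in replicates 1 and 2. The next was U 6071086-6072996 (0.79, with 0.99 and 1.74). The highest on an arm was X 11956608-11959262 (0.73, with 0.83 and 0.83), followed by X 1464852-1467512 (0.71, with 0.79 and 0.79) and X 20268504-20271240 (0.70, with 0.67 and 1.05). The highest on 3L was 1711384-1714828, at 0.64. The other 4 clusters scored between 0.63 and 0.68.

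The longest series-wide cluster that overlapped both replicates was 3L 22328194-22340330, of 12137 bp, outside the 2 Mb next to the centromere of that arm. It spanned 4 clusters of replicate 1 and 1 of replicate 2. X 1420186-1429682 followed with 9497 bp, 2L 14601236-14610500 with 9265 bp, 3R 18329954-18338402 with 8449 bp and 3R 698648-706912 with 8265 bp. The other 5 measured 7377 to 7779 bp, and all 10 scored between 0.42 and 0.57. The longest clusters of 1 replicate alone were 3R 5481740-5486705 in replicate 1 (4966 bp, score 0.61) and 3L 5832760-5837072 in replicate 2 (4313 bp, score 0.72). Each of the 5 longest such clusters in either replicate overlapped a cluster of the series-wide list.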

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

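The alternatives added after the data were examined were local shifts, length and score differences beyond those of shifted lists, a minimum length, Uextra in the lengths, correlations by chromosome, and all those of the X comparisons and the centromere ends. Of 161 alternatives to 25 results, 133 were classed as unchanged. For results with a test this meant the same direction and the same side of the threshold. Ratios by covered bases had to stay within the exact binomial interval of the ratio by clusters. Number, covered Mb and median length of clusters had a looser margin, not a spread. Thus 14012 merged clusters against 18424, and 22.4 Mb at the minimum length against 30.4 Mb, counted as unchanged. The removal of clusters under 200 bp, which could change nothing, is also among the 133. Excess overlap between the replicates held in every alternative run. That with the series-wide list held too, but it was built in, since by its name this list is a set of the same replicates. The upper 50% by score held 9212 series-wide clusters over 15.5 Mb, and turned the ratio to length to 0.870 on 2L, 0.947 on 3L and 1.52 on X, and the density of X over the autosome arms to 1.50. With the 6 arms alone, 2L fell to 0.956 and 3L to 0.974, while 2R at 1.12, 3R at 1.15 and X at 0.826 kept their direction. X moved to 0.988 with neighbours merged, no longer past the threshold (exact binomial test, adjusted p = 0.55), and to 1.12 with Uextra in the lengths. By covered bases, 2R stood at 1.31 and U at 0.181. A minimum length of 1301 bp left 11350 series-wide clusters. Each replicate alone gave 2198 to 3717 clusters, 3.48 to 6.06 Mb, and ratios of 0.975 to 1.06 on 2L, 1.05 to 1.12 on 3L and 0.833 to 0.930 on X. The score difference in replicate 2 between shared and unshared clusters, never past the threshold, became -0.0036 with reciprocal 50% overlap and -0.003 with 50% of the counted cluster. Beyond the differences of shifted lists, shared clusters of replicate 1 were longer by 67.5 bp, and beyond those of locally shifted lists by 57.4 bp in replicate 1 and 39.5 bp in replicate 2, with scores higher by 0.015 in replicate 1, all with an adjusted permutation p of 0.051. The rank correlation of scores on X alone was 0.223 (p = 0.069), on 67 pairs, while Pearson's r was 0.265 (p = 0.029). Fewer clusters entered the shorter lists by construction. Restriction to the 6 arms, or Uextra in the lengths, scales the ratios of all arms by the same factor. The turns of 2L, 3L and X under these 2 choices thus follow from the sequences counted. The turn of X in the upper 50% by score follows from the higher scores on X. For the remaining changes the cause was not tested. No paired analysis was possible because each input enters only through the cluster call of its ChIP replicate and has no list of its own here. The alternatives planned for gene features, gene lists and base composition were not run. Unknown read depth leaves open whether the shorter list of replicate 2 reflects fewer reads.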

Other observations

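Of the tests in this part, those on chromosome 4 and on the X scores, the distances between replicate clusters, the choice of windows and the matching within sequence classes were chosen only after the results were seen. For the clusters of highest score, 2 readings were also tightened after the values were seen. At least 5 expected overlaps were required on the arms, and short length was not excluded unless both ways of matching passed the threshold.

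Of the 3140 replicate 1 clusters on the arms that overlapped none of replicate 2, 682 (21.7%) lay within 5 kb of a replicate 2 cluster. After local shifts, which keep the regional density, the share among the clusters that did not overlap was 19.5% (central 95% 18.2 to 20.7, ratio 1.12, one-sided permutation p = 0.001, the smallest possible). The number itself missed the threshold, at 682 against 660.1 after local shifts (ratio 1.03, permutation p = 0.18), and the share rests on fewer clusters without overlap than the 3389 of the shifted lists, so closeness beyond overlap was not shown. By share, at 5 to 10 kb the ratio was 1.02 (permutation p = 0.33) and at 10 to 20 kb it was 0.943 (permutation p = 0.95). The window 3L 22000001-23000000 held 179 series-wide clusters with 48 and 28 in the replicates, between 163, 26 and 18 in the window before it and 35, 4 and 1 in the window after it. The window X 1000001-2000000 held 197, 58 and 38, between 120, 33 and 22 before it and 171, 32 and 27 after it.

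Of the 13253 series-wide clusters listed in neither replicate, 6616 (49.9%) were at least as long as the shortest replicate cluster, and 7313 (55.2%) scored under the 5th percentile of both replicate lists. Scores of separate lists need not share a scale.

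Clusters were rare on chromosome 4. Long unmappable stretches could leave islands of usual cluster density. The median gap between neighbouring clusters was 36.2 kb on 4 and 2.64 kb on the autosome arms, a ratio of 13.7 (95% bootstrap interval 4.01 to 53.9). This argues against islands that each hold several clusters at the usual spacing. Islands with about 1 cluster each would give such gaps as well. The part on which reads could be placed was not measured, so unmappable sequence stays open. Lower read depth at each cluster could raise the scores needed there, but the score ratio to the autosome arms on 4 minus that on X was -0.10 (-0.21 to 0.024), and with 17 clusters this stays open. Short repeats along the whole chromosome could shorten clusters, and the length ratio of 0.888 (0.758 to 1.08) leaves that open too. No biological explanation was tested, since the design has 1 stage and 1 strain.

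Scores were higher on X. Fewer X reads in a population of both sexes could raise the score that a cluster needs, and an equal log2 step of H3 enrichment on X would also give higher scores. The difference from the autosome arms was larger in replicate 2 than in replicate 1 by 0.041, or 1.51 times, but this sets 1 library against 1 library and decides neither. Both stay open, as does a step that scales with the scores of each replicate, with X over autosome ratios of 1.15 and 1.18. Under a shared score threshold, either step alone would add clusters on X. Yet X had fewer clusters per Mb in every list. Its 5th percentile of score was higher by 0.057 in the series-wide list, 0.072 in replicate 1 and 0.11 in replicate 2, which either step could also give. The threshold used is not known. The lowest scores of the lists were 0.085, 0.22 and 0.30, far below the 5th percentiles of the autosome arms (0.31, 0.41 and 0.52). No shared score threshold was thus visible, and the fewer clusters on X decide neither. The sex of the embryos is not given in the labels.

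The highest-scored clusters of the series-wide list seldom repeated. Of the 185 clusters in the top 1% by score, 116 lay on U, and 14 (7.57%) overlapped a replicate cluster, against 28.3% of all others. Short length may account for this: clusters matched on length overlapped in 12.1% of cases (central 95% of draws 8.11 to 16.8, two-sided permutation p = 0.043), but matched on length within the arms and within U and heterochromatin they overlapped in 10.1% (6.49 to 14.1, permutation p = 0.27). Unplaced or heterochromatic sequence may also contribute: on the 6 arms 5 of 41 such clusters (12.2%) overlapped, against 10.2% when matched on length (permutation p = 0.83), and in U and heterochromatin 6.25% against 10.0% (permutation p = 0.13). Under the rules written first, short length alone would have been excluded and unplaced sequence favoured, but the first matching mixed sequence classes and fewer than 5 overlaps were expected on the arms, so both stay open, and no biological explanation was tested.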
